A study of Mus musculus with 2 samples.

How the data were processed

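Gene expression in the airway epithelium of fetal mouse lung was measured on 1 two-colour oligonucleotide array. Per the labels' protocols, frozen lungs of wild-type male CD-1 fetuses were sectioned, the epithelium lining the airways inside the lobes was cut out with a laser, and the pieces from 1 lung at embryonic day 14.5 (E14.5) and 1 lung at E18.5 were collected. RNA of each age was amplified in a single round. Per the labels, the E14.5 material carried Cy3 (green) and the E18.5 material carried Cy5 (red), and both were hybridised together. The sample groups come from the sample titles, with 1 sample per group. The scanner outputs given for the 2 samples were identical in 115 of 115 columns, so they were read as 1 array, green for E14.5 and red for E18.5.

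The scanner tables hold the mean intensity and the median local background intensity of each spot in each channel, linear and without background subtraction, as deposited by the authors. Per the file headers, they were made with Agilent Feature Extraction, version 9.5.3.1 per the submitters' processing notes. The same tables hold processed intensities and a log10 ratio of red over green, which the scanner software made by background subtraction and dye normalization, per the file headers. Flags of 0 or 1 for outlier spots, saturation and spots well above background are also the deposited ones of that software. Probe coordinates are on the build that the file headers name as mm8. The authors' value table holds linear intensities: on comparison with the scanner output, each of its columns was the processed intensity of the sample's own channel times 0.339, with values under 15 set to 15, and it was not centred. Its column medians were 129 at E14.5 and 130.2 at E18.5, and 10944 and 10827 probes stood at the floor. Its scale, centring and direction are therefore known, and the origin of the constant is not given in the sources used here.

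For the main values, the mean intensities were background-corrected with normexp and an offset of 50, and the log2 ratio of red over green was normalized within the array by loess (span 0.3, 4 iterations), in limma 3.58.1 under R 4.3.3. Control spots and outlier spots had weight 0 in the loess curve and were then left out. The offset pulls the ratios of dim genes towards 0. Loess moves the centre of the log ratios towards 0 at each intensity, so a shift common to most genes would not be seen. At the bright end it stayed above 0: the 65 gene probes within 0.25 of the average log2 intensity of the brightest spike-in probe had a median log2 ratio of 0.46. The array held 45018 spots, of which 1639 were controls and 43379 carried probes. Of the probe spots, 160 were outliers, which left 41170 probes of 60 bases. Repeated spots of a probe were averaged. No probe was saturated (0 probes). Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

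Probe names were updated through a table of mouse RefSeq genes of assembly GRCm38.p6, used for names only. It named 33113 probes, 24426 of them by a transcript accession, 6301 by the current symbol and 2386 by an older symbol, and these stood for 19752 genes. The other 8057 probes kept the name in the file, stood for 7836 transcripts and were counted separately. Where a gene had several probes, the one with the highest average log2 intensity among those well above background in at least 1 channel was used. Where a probe was well above background in 1 channel only, its ratio is a bound, written as "at least N-fold": the bright channel's normalized signal over the higher of the dim channel's lowest signal among probes well above background and the dim spot's own signal. Such bounds are open to dye bias, since no dye swap was made. A probe dim in both channels gave no ratio. Probes of 60 bases can also bind near-identical copies, so values of the globin, lysozyme, metallothionein and Hspa1a families may mix several genes.

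Depth on an array is signal over background. The median background-subtracted signal of probe spots was 256 at E14.5 and 308 at E18.5, and the 153 negative control spots had means of 45.9 ± 4.33 (SD) and 23.8 ± 4.79 (SD). Of the probes, 75.2% were well above background at E14.5 and 78.6% at E18.5. The number of arrays, 1, limits the precision. With 1 sample per age there is no replicate check of any difference, dye and age were not separated, and no p-value was computed. Calls were made by size alone, at 2-fold or more. The only spreads that could be measured were technical: the SD of the log2 ratio over at least 3 repeated spots of a probe, and the SD between different probes of a gene.

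Before the data were examined, 25 gene lists with 651 genes were fixed, together with the rule for the genes named below. That rule takes Foxj1, the 15 genes with the largest and the 15 with the smallest log2 ratio among those measured in both channels with the same sign in the scanner software's ratio, the 5 largest bounds in each direction, the 4 members of each list with the ratio farthest from 0 (of which 2 to 4 are given), and all measured reference and sex chromosome genes. Genes known only by a clone, model or accession name were passed over, which met 0 genes among the largest, 0 among the smallest, 1 among the bounds for higher genes and 1 among those for lower genes. A few further genes are named where the text says that they were chosen after their values were seen. For each list, members were counted by size, and the median log2 ratio was placed among 10000 random lists of the same size matched on average log2 intensity in 20 bins. That percentile describes this array, and genes are not replicates. A few genes that this rule takes are not reported here by name, though they remain in the counts. Symbols follow the reference table, which still prints some older forms such as Dnaic1.

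The steps were tested on simulated data built for the E18.5 over E14.5 comparison, with 17242 genes, a dye curve of up to 0.60 on the log2 scale, and 200 genes altered by known folds. All 100 of 100 genes altered 3-fold and 100 of 100 altered 8-fold were called in the true direction, with median recovered log2 sizes of 1.59 and 2.97 against true sizes of 1.58 and 3. The altered genes were few and evenly split between directions, whereas the real array had 2988 higher and 1739 lower genes. This recovery therefore does not test loess where many genes differ unevenly. Among 17042 unaltered genes, 0 were called. Their log2 ratios had an SD of 0.16, below the median SD of 0.33 between probes of a gene on the real array. The 0 calls therefore say little about false calls there. Of 200 lists of 30 genes drawn at random from the real values, 7 lay outside the middle 95% of random lists, and after a shift of 1 on the log2 scale 200 of 200 lay above it. The simulated noise covers spot error alone.

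Alternatives were an offset of 10, no background correction, median centring in place of loess, the scanner software's log ratio, the authors' value table, no filter on dim probes, a filter to probes well above background in both channels, the median over a gene's probes, and thresholds of 1.5-fold and 3-fold. Transcripts without a name in the reference table were left out of the gene counts. Spike-in and negative control spots entered no gene count.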

Results

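The study looked for effectors of FOXJ1, a transcription factor of motile ciliogenesis, and its lung part set the airway epithelium of mouse fetuses at E14.5 against that at E18.5. Each age was represented by laser-dissected airway epithelium from 1 lung, and both were measured on the same array. A ratio or a bound was obtained for 17245 genes. By the probe used, 16319 were well above background at both ages, 733 at E18.5 only and 193 at E14.5 only. Another probe of a gene could differ in this. The log2 ratios below are E18.5 over E14.5, from the E18.5 material in red and the E14.5 material in green. All differences are between these 2 samples, without a replicate check or a dye swap.

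Foxj1 itself had a log2 ratio of 2.19, a 4.55-fold higher intensity at E18.5 (22922) than at E14.5 (5039). Its signal came from 1 probe, on chromosome 11 from 116146990 to 116147049 on mm8, and the scanner software's own log2 ratio for it was 2.02. Over all genes, 2988 (17.3%) were at least 2-fold higher at E18.5, 108 of them by a bound, and 1739 (10.1%) were at least 2-fold lower, 13 of them by a bound. The other 12518 genes lay within 2-fold. The difference between directions was wider among large ratios: 546 genes were at least 8-fold higher and 73 at least 8-fold lower. The median log2 ratio over genes was 0.06. Among 4610 transcripts without a name in the reference table, 347 were at least 2-fold higher and 354 at least 2-fold lower. With the scanner software's ratio, 2638 genes were at least 2-fold lower, more than 1.5 times the main count.

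Repeated spots of a probe agreed closely, with a median SD of the log2 ratio of 0.04 over 202 probes. Different probes of a gene were further apart, with a median SD of 0.33 over 6895 genes, and 25 genes had probes at least 2-fold apart from 0 in opposite directions. Neither spread covers differences between animals, dissections or amplifications.

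**Figure D1:**
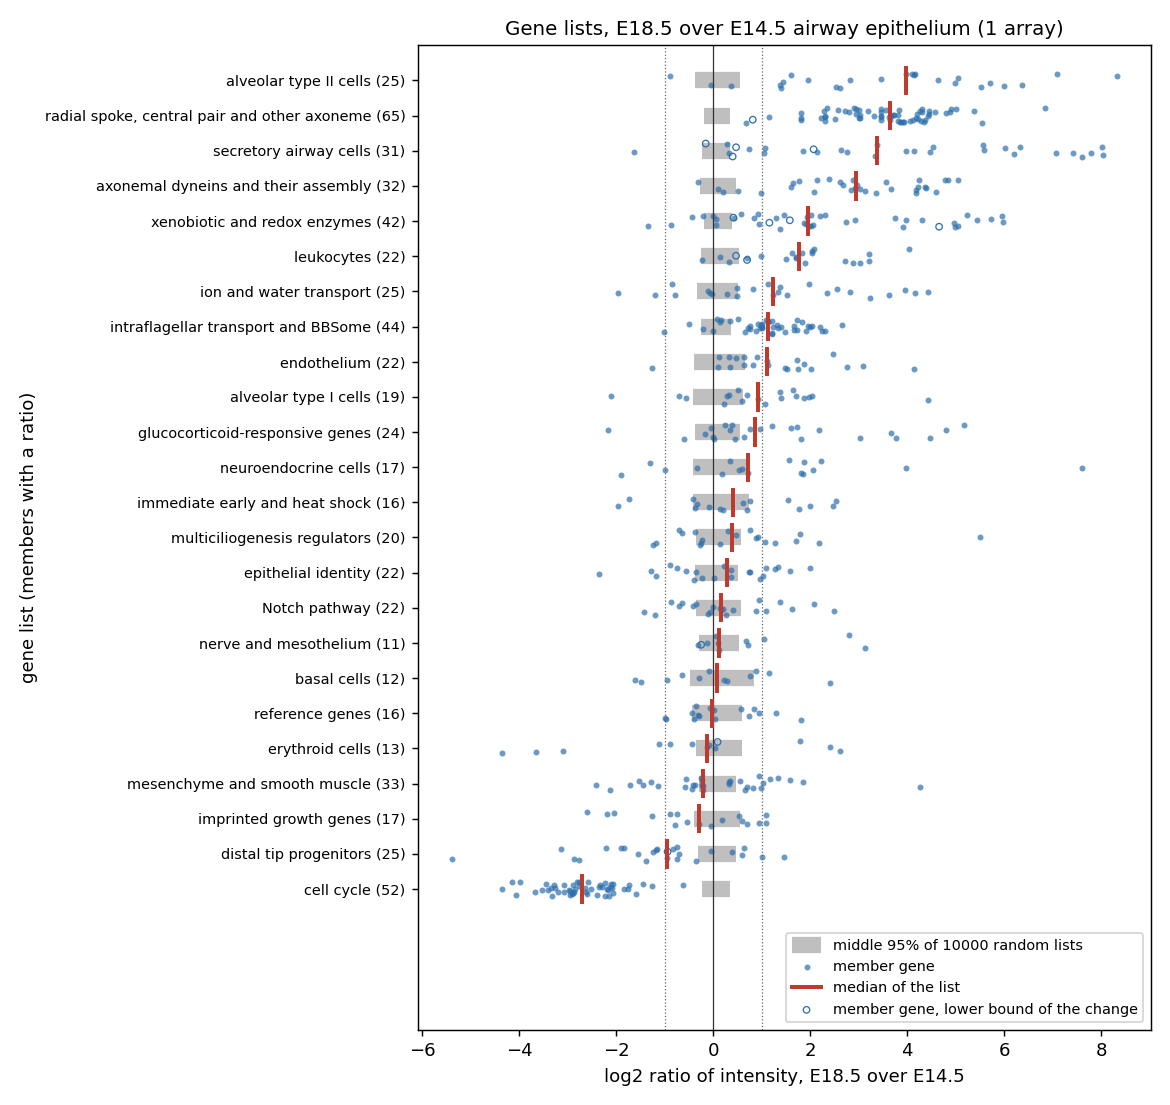
Log2 ratio of intensity at E18.5 over E14.5 (horizontal axis) for the members of 24 gene lists (rows, with the number of members that had a ratio). Points are genes, open points are bounds, red lines are list medians and grey bars span the middle 95% of random list medians; dotted lines mark 2-fold. The median was −2.71 for the cell cycle list, the lowest, and 3.96 for the alveolar type II list, the highest.

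Genes that build motile cilia were higher at E18.5 nearly throughout. Of 65 genes for radial spokes, the central pair and other parts of the axoneme, 63 were at least 2-fold higher, 0 were at least 2-fold lower and 2 lay within 2-fold. The largest ratios belonged to Sntn, which encodes a protein of the ciliary tip (log2 ratio 6.85, 115-fold), Ak7, an adenylate kinase of the axoneme (5.54, 46.4-fold, with another probe at 0.66), Rsph14 (5.37, 41.4-fold) and Hydin, a central pair protein (5.01, 32.1-fold). Sntn was near the floor at E14.5, with an intensity of 102, so its fold depends on the background correction, and the scanner software's log2 ratio was 8.14. In the same comparison, epithelial identity genes had a median of 0.29 and leukocyte and endothelial genes medians of 1.77 and 1.11. The axoneme list median was 3.64, above those of all 10000 random lists (percentile 100). Among 32 axonemal dyneins and factors that assemble them, 27 were at least 2-fold higher, 0 lower and 5 within 2-fold, with a median of 2.94 (percentile 100). The dynein heavy chains Dnah9 (5.04), Dnah2 (4.83), Dnah5 (4.78) and Dnah6 (4.58) led this list, but other probes of Dnah9, Dnah2 and Dnah5 had log2 ratios as low as 0.16, 0.01 and 0.23. With the median over probes, Dnah9 and Dnah2 came to 0.31 and 0.06, within 2-fold.

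Intraflagellar transport and BBSome genes, which serve primary as well as motile cilia, had smaller ratios. Of 44 members, 27 were at least 2-fold higher, 1 lower and 16 within 2-fold, and the median was 1.12 (percentile 100). Ttc30b (2.66, 6.31-fold), Ift46 (2.31, 4.96-fold) and Dync2h1, the motor of retrograde transport (2.24, 4.72-fold), were farthest from 0. One Ift46 probe lay at 0.45 and one Dync2h1 probe at 0.14. The regulators of multiciliogenesis were mixed: of 20 members, 6 were at least 2-fold higher, 2 lower and 12 within 2-fold, with a median of 0.38 (percentile 89.8). Beside Foxj1, the members with the largest ratios were Ccdc78, a component of deuterosomes (5.49, 45.0-fold), Cep63, a centriole duplication factor (1.79, 3.45-fold), and Ulk4 (1.71, 3.27-fold). The 2 lower members, named after their values were seen, were Plk4 (−1.23, other probe −0.07) and Cep152 (−1.19). This list joins transcription factors with centriole amplification genes. Of its 22 listed genes, 20 were found on the array, and Mcidas and Gmnc were not.

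**Figure D2:**
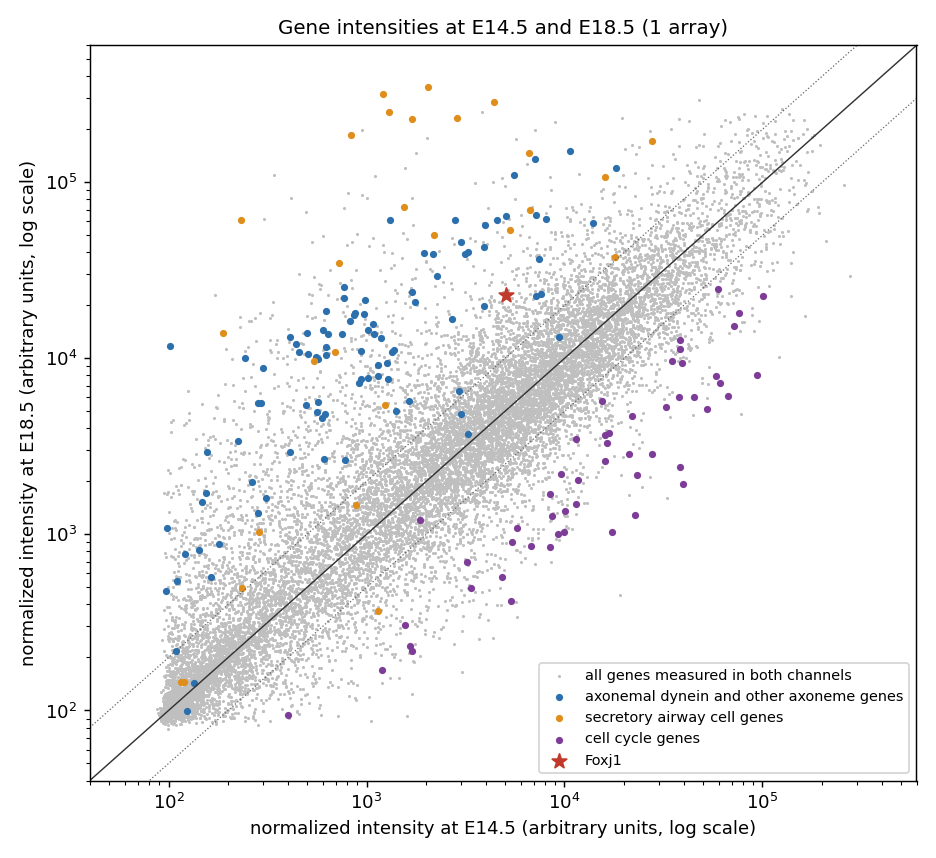
Normalized intensity at E14.5 (horizontal axis, arbitrary units, log scale) and at E18.5 (vertical axis, arbitrary units, log scale) for each gene measured in both channels (grey), with axonemal genes, secretory airway cell genes, cell cycle genes and Foxj1 (star) in colour. The solid line is equality and dotted lines mark 2-fold; of the cell cycle genes 51 of 52 lie below the lower dotted line, and Foxj1 lies at 5039 and 22922.

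Products of secretory airway cells made up much of the top of the ranking. Of 31 members of the list, 24 were at least 2-fold higher (1 by a bound), 1 lower and 6 within 2-fold, with a median of 3.38 (percentile 100), beside medians of 1.77 and 1.11 for leukocyte and endothelial genes. Scgb1a1, the secretoglobin that marks club cells, had a log2 ratio of 8.03 (262-fold), with its probe on chromosome 19 from 9150752 to 9150811 on mm8. Pon1, an esterase (8.02, 260.3-fold), Sec14l3 (7.80, 222-fold, with another probe at 5.67) and Cyp2f2, a club cell cytochrome P450 (7.60, 194-fold), followed. Muc5ac, a gel-forming mucin, was the member lower at E18.5, at −1.62 by the probe used and 0.10 by its other probe, and was named after its value was seen.

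Genes of alveolar type II cells were also higher, in material dissected as airway epithelium. Of 25 members, 22 were at least 2-fold higher, 0 lower and 3 within 2-fold, with a median of 3.96 (percentile 100). Sftpd, which encodes surfactant protein D and is also made in airways, had the largest ratio of all genes in the main setting (8.33, 322-fold), with its probe on chromosome 14 from 40080953 to 40081012 on mm8. Lyz1 (7.09, 136-fold), Lyz2 (6.38, 83.1-fold, other probe 4.32) and Lcn2 (64.0-fold), which encode lysozymes and lipocalin 2, came next. Leukocytes, which also make lysozyme and lipocalin, had a median of 1.77 over their own list. Further type II members, named after their values were seen, included Slc34a2 (5.70, other probe 2.38) and Sftpb (3.96). Ratios were smaller for Abca3 (2.61, other probes 0.19 and 3.77), Sftpc (2.54, 5.81-fold), Lamp3 (1.96, another probe 0.42) and Lpcat1 (0.36). Sftpc was already bright at E14.5, with an intensity of 34625. Among 19 genes of alveolar type I cells, 9 were at least 2-fold higher, 1 lower and 9 within 2-fold, with a median of 0.92 (percentile 99.8). Aqp5, a water channel, was at 4.43 (21.6-fold, 5.03 by the scanner software), Hopx at 2.04 (4.13-fold), Ager at 1.97 (3.92-fold) and Igfbp2 at −2.11 (4.31-fold lower).

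Cell cycle genes were lower at E18.5 with 1 exception in size. Of 52 members, 0 were at least 2-fold higher, 51 at least 2-fold lower and 1 within 2-fold. The median was −2.71, below those of all 10000 random lists (percentile 0), beside a median of −0.21 for mesenchyme and smooth muscle genes, which went both ways: 6 contractile genes of smooth muscle, set apart after the values were seen, had a median of −1.48 and the other 27 a median of 0.32. Uhrf1, which recruits DNA methyltransferase at replication, was 20.4-fold lower (−4.35), Nusap1, a spindle protein, 17.6-fold lower (−4.14, other probe −2.26), Bub1, a checkpoint kinase, 16.9-fold lower (−4.08), and Ube2c, a mitotic ubiquitin-conjugating enzyme, 15.8-fold lower (−3.98). The single member within 2-fold, named after its value was seen, was E2f1 at −0.62, with its other probe at −1.22.

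Genes of the distal tip progenitors of the branching lung were lower on balance. Of 25 members, 2 were at least 2-fold higher, 12 lower and 11 within 2-fold, with a median of −0.95 (percentile 0). Mycn, a growth-promoting transcription factor of the tip epithelium, had the lowest ratio of all genes in the main setting (−5.40, 42.1-fold lower), with the probe used on chromosome 12 from 12962373 to 12962432 on mm8. Its second probe was at −2.18. Hmga2 (−3.15, 8.86-fold lower), the claudin Cldn6 (−2.88, 7.37-fold lower) and the transcription factor Etv5 (−2.78, 6.86-fold lower, −3.43 by the scanner software) were next. Of the members, 20 lay below 0 and 5 above. Those above, named after their values were seen, were Lgr5 (1.45), Spry4 (1.00), Dusp6 (0.63), Bmp4 (0.59) and Spry2 (0.39). Spry4 was dim at E14.5, with an intensity of 139. Basal cell genes showed no common direction: 2 of 12 were at least 2-fold higher, 2 lower and 8 within 2-fold, with a median of 0.07 (percentile 44.5) that changed sign to −0.11 with the scanner software's ratio (0.00 relative to its shift of all genes). Within that list the keratin Krt15 was at 2.40 (5.28-fold) and Trp63, the basal cell transcription factor, at −1.61 (3.05-fold lower, other probe −0.48). Of 17 neuroendocrine genes, 8 were at least 2-fold higher, 2 lower and 7 within 2-fold, with a median of 0.72 (percentile 97.2). Calca, which encodes calcitonin and its gene-related peptide, was at 7.60 (194-fold) by its brighter probe and 4.19 by the other, and the granule proteins Resp18, Chgb and Chga were at 3.97, 2.23 and 2.06.

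Genes of general epithelial identity were mixed, with 6 of 22 at least 2-fold higher, 3 lower and 13 within 2-fold, and a median of 0.29 (percentile 85.5). The transcription factor Elf5 was at 1.99 (3.97-fold), the keratin Krt18 at 1.59 (3.02-fold), E-cadherin (Cdh1) at 1.34 (2.53-fold) and Cdh16 at −2.36 (5.14-fold lower).

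Genes of cell types outside the epithelium were measured in the same material. Leukocyte genes were higher at E18.5, with 15 of 22 at least 2-fold higher, 0 lower and 7 within 2-fold, and a median of 1.77 (percentile 100). The calprotectin genes S100a8 (4.04, 16.5-fold) and S100a9 (3.21, 9.24-fold), Ptprc, the pan-leukocyte antigen CD45 (3.21, 9.23-fold, other probe 0.53), and the macrophage receptor Mrc1 (3.03, 8.19-fold) led. S100a8 and Ptprc were dim at E14.5, with intensities of 116 and 148, so their folds depend on the background correction, and the scanner software's log2 ratios were 5.41 and 3.92. Of 22 endothelial genes, 12 were at least 2-fold higher, 1 lower and 9 within 2-fold, with a median of 1.11 (percentile 99.9). Kdr, a receptor for vascular endothelial growth factor, was at 4.13 (17.5-fold), and von Willebrand factor (Vwf) at 3.08 (8.48-fold). Members within 2-fold, named after their values were seen, included Pecam1 (0.64), Cdh5 (0.35), Eng (0.12) and Tie1 (0.09). Mesenchyme and smooth muscle genes went both ways: 6 of 33 were at least 2-fold higher, 7 lower and 20 within 2-fold. Their median was −0.21 (percentile 6.54) and their mean 0.04, of opposite sign. The matrix genes Dpt (4.27, 19.3-fold) and Eln (1.86, 3.63-fold) stood against Myh11, smooth muscle myosin (−2.43, 5.37-fold lower), and the mesenchymal transcription factor Foxf1 (−2.12, 4.36-fold lower, −2.75 by the scanner software). Among 11 nerve and mesothelium genes, 3 were at least 2-fold higher, 0 lower and 8 within 2-fold, with a median of 0.13 (percentile 66.3). The mesothelial genes Msln (3.13, 8.76-fold) and Upk1b (2.79, 6.93-fold) were farthest from 0.

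Erythroid genes went both ways. Of 13 members, 3 were at least 2-fold higher, 4 lower and 6 within 2-fold, with a median of −0.13 (percentile 16.2). The embryonic globins Hbb-y (−4.35, 20.4-fold lower), Hba-x (−3.65, 12.5-fold lower) and Hbb-bh1 (−3.11, 8.62-fold lower) were lower at E18.5, and the adult beta globin Hbb-bt was higher (2.60, 6.08-fold). Members other than globins, named after their values were seen, also went both ways, such as Alas2 (1.78) and Klf1 (−1.12). Hbb-bh1 was near the floor at E18.5 (intensity 119), so its size depends on the background correction, and the scanner software's log2 ratio was −4.44. Probes for the adult globins can bind more than 1 copy.

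Enzymes that handle xenobiotics and redox stress were higher as a group. Of 42 members, 29 were at least 2-fold higher (3 by a bound), 1 lower and 12 within 2-fold, with a median of 1.95 (percentile 100), in material where leukocyte and endothelial genes had medians of 1.77 and 1.11. The sulfotransferase Sult1a1 was at 5.96 (62.5-fold), Cyp4b1, a lung cytochrome P450, at 5.95 (61.9-fold), the aldehyde oxidase Aox3 at 5.74 (53.3-fold) and the flavin monooxygenase Fmo2 at 5.43 (43.3-fold). Of 25 genes for ion and water transport, 14 were at least 2-fold higher, 2 lower and 9 within 2-fold, with a median of 1.24 (percentile 100). These included Scnn1a, a subunit of the epithelial sodium channel (4.15, 17.8-fold, with a second probe at 1.04), and the water channels Aqp4 (3.94, 15.4-fold) and Aqp1 (3.63, 12.4-fold). Aqp1 is also made by endothelium, whose list had a median of 1.11. Cftr, the chloride channel, was at −1.97, and was named after its value was seen. Of 24 genes that respond to glucocorticoids, 11 were at least 2-fold higher, 1 lower and 12 within 2-fold, with a median of 0.87 (percentile 99.9). That median was below those of leukocyte and endothelial genes. Hsd11b1, the enzyme that regenerates active glucocorticoid, was at 5.17 (36.1-fold), the metallothionein Mt2 at 4.80 (27.9-fold) and the transcription factor Klf15 at 4.47 (22.1-fold, other probe 2.01). Among the 12 members within 2-fold were Tsc22d3 (0.97), Fkbp5 (0.007, another probe 0.44) and Per1 (0.004), named after their values were seen.

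Of the 15 genes with the largest ratios, several lay outside the lists. The iron and copper carriers Trf (7.71, 209.8-fold) and Cp (6.75, 107.7-fold) were among them, as were Tmem212 (7.68, 204.9-fold), Fam216b (7.05, 132.6-fold) and the secreted protein Retnla (6.62, 98.2-fold). The secretory cell products Scgb3a2 (7.42) and Hp, haptoglobin (7.08), completed that set. Among the 15 genes with the smallest ratios outside the lists were the galactosyltransferase B3galt5 (−4.20), Cer1, a secreted antagonist of Nodal and BMP (−4.11), the DNA glycosylase Neil3 (−4.07, with another probe at −1.42), Lrr1 (−4.06), lamin B1 (Lmnb1, −4.02), complement factor I (Cfi, −3.80), the cohesin subunit Stag3 (−3.78) and Shcbp1 (−3.72). Cer1, B3galt5 and Stag3 were dim at E18.5, with intensities of 93, 166 and 124, so their sizes depend on the background correction, and the scanner software's ratios were −6.12, −5.25 and −5.21. The scanner software's ratios also lay farther from 0 for Lrr1 (−4.66) and Fam216b (7.70). Genes well above background at E18.5 only, by the probe used, included Spink5 (at least 23.9-fold higher), Fpr2 (at least 18.2-fold, other probe 1.72 on the log2 scale), Mlc1 (at least 17.3-fold) and Ces1b (at least 16.1-fold). Those well above background at E14.5 only, by the probe used, were led by Arl14 (at least 5.18-fold lower), Camkv (at least 4.40-fold), Tbc1d24 (at least 4.33-fold), Ankrd22 (at least 3.63-fold) and Raet1d (at least 3.59-fold). A second Camkv probe, measured at both ages, was at −0.98.

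Both samples, labelled male, carried signal from genes of the Y chromosome. Log2 ratios were 0.69 for Ddx3y, 0.64 for Eif2s3y, 0.15 for Uty and −0.07 for Kdm5d. Xist was at 0.05, with intensities of 106 and 110 close to the floor in both channels. The 5 measured genes of this set all lay within 2-fold, with a median of 0.15 (percentile 64.1).

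Reference genes that are often used as controls were not uniform. Of 16, 2 were at least 2-fold higher, 0 lower and 14 within 2-fold, and the median of −0.02 (percentile 39.0) changed sign to 0.13 with median centring. Rplp0 was at 1.81, with another probe at 0.44. Gapdh was just inside 2-fold, with intensities of 177241 at E14.5 and 88738 at E18.5, and Tfrc was at −0.98. Values above 0 were 0.94 for Rpl13a, 0.85 for Ywhaz (other probe −0.66), 0.74 for Hprt and 0.56 for B2m. Values below 0 were −0.40 for Ppia, −0.36 for Polr2a, −0.31 for Sdha and −0.29 for Tbp, of which Ppia changed sign with median centring (0.12). Actb (−0.06), Pgk1 (0.04) and Gusb (0.02) were closest to 0.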

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

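The comparisons of leukocyte with mesenchyme and endothelial genes, those of the 3 medians with random lists as a test of dye bias, those with the probes of all genes, the split of the mesenchyme list and the gene probes near the brightest spike-in were chosen after values were seen. Among all genes with several probes measured at both ages, 65.8% had all of them on one side of 0, and among those with a probe at least 2-fold from 0, 79.4%. With 1 sample per age, there was no other sample of a group to compare with, and no count over other splits of the samples was possible.

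The spike-in control spots entered no comparison above, and they carried signal. All 10 spike-in probes, each with 27 to 32 usable spots, exceeded the mean of the negative control spots by more than 3 SD in both channels. The log2 ratio of the brightest was 1.06 ± 0.07 (SD over spots), against −0.31 to 0.11 for the other 9. With median centring in place of loess, the ratios at the bright end rose with intensity, through −0.02, 0.25 and 0.51 to 1.62. The cause of this rise was not tested. The amounts added to each sample are not given in the sources used here. The 65 gene probes within 0.25 of the average log2 intensity of the brightest spike-in probe had a median log2 ratio of 0.46 in the main setting.

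Motile cilia genes were higher at E18.5, with a pooled median of 3.02 over the 117 genes of the regulator, dynein and axoneme lists. The regulator list alone had a median of 0.38 (percentile 89.8), so the pooled values speak mainly for dynein and axoneme genes. Random lists matched on the base composition and intensity of the probes had medians between −0.12 and 0.28 in their middle 95%, and the observed median was at percentile 100 of them, which argues against base composition. A larger share of epithelium in the E18.5 piece would raise epithelial identity genes by as much. The cilia median was higher than theirs by 2.73 (95% bootstrap interval over genes 2.11 to 3.70). Both pieces were cut as epithelium, and this comparison does not tell which parts of the epithelium each held. Alveolar type II genes had a median of 3.96 and distal tip progenitor genes one of −0.95. In 37 of 44 genes with several such probes (84.1%) all probes lay above 0, between the 75% and 90% set beforehand, which decided nothing. Among all genes with a probe at least 2-fold from 0, the share with all probes on one side was 79.4%. Random lists matched on intensity, which carry the same differences between probes, had medians between −0.12 and 0.27 (observed at percentile 100). The percentiles of the lists were known when that comparison was chosen, so it is no independent test. Dye bias of single probes was not decided. A dye effect on individual genes stays open without a dye swap, as does an effect of age, which 1 lung per age does not test. A difference between the 2 lungs or dissections that is unrelated to age also stays open.

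Cell cycle genes were lower at E18.5, with a median of −2.71. Less mesenchyme in the E18.5 piece would lower mesenchymal genes by as much, but their median was higher by 2.50 (95% bootstrap interval over genes 2.13 to 3.32), which argues against it as the whole cause. Contractile genes of smooth muscle, set apart after the values were seen, were lower as well (median −1.48, 6 of 6 below 0, against 0.32 for the other 27), so a smaller share of smooth muscle stays open for part of the pattern. In 20 of 20 cell cycle genes with several such probes (100%) every probe lay below 0, which argues against dye bias of single probes. A second Cenpa probe, dim at E14.5 and so not counted, gave a bound of 0.09. The median was at percentile 0 of random lists matched on intensity (−0.24 to 0.36), which was known when that comparison was chosen. An effect of age was not tested and stays open, as does a difference between the 2 lungs or dissections that is unrelated to age.

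Leukocyte genes were higher at E18.5, with a median of 1.77. A larger share of every non-epithelial cell type would raise mesenchymal genes alike, but the leukocyte median was higher than theirs by 1.98 (95% bootstrap interval over genes 1.01 to 2.37). Without 6 contractile genes, set apart after the values were seen, the other 27 mesenchymal genes had a median of 0.32. No interval was computed for the leukocyte median against these 27. The leukocyte median was higher than the endothelial median of 1.11 by 0.66 (−0.19 to 1.32), an interval that includes 0. A larger share of leukocytes and endothelium together therefore stays open. Endothelial genes did not rise alike: 12 of 22 were at least 2-fold higher and 9 within 2-fold, among them Cdh5 (0.35) and Tie1 (0.09). Of the 3 genes with several such probes, 2 (66.7%) had all probes above 0, under the 75% set beforehand as pointing to dye bias. That share was near the 65.8% and under the 79.4% of all genes. The 3 genes were taken as too few to decide, by a minimum the prediction did not state. The median was at percentile 100 of random lists matched on intensity (−0.26 to 0.55). That percentile was known when the comparison was chosen, so it is no independent test. Dye bias of single probes stays open for this list. Expression of some of these genes by the epithelium itself, an effect of age and a dye effect on individual genes were not tested and stay open.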

How the results depend on the processing

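The spread used for a shift of a list median or gene was the SD between probes of a gene (0.33 on the log2 scale), chosen after the SD between repeated spots proved too small (0.04) to serve; the technical spread under other settings was also added after seeing the data. Under it, shifts smaller than 0.33 are not listed. No gene at least 2-fold changed in the main setting was at least 2-fold changed in the opposite direction under an alternative (0 opposite calls in each of the 8). No paired analysis was possible because each age had 1 sample. Depth limits the dim end: 8160 probes were dim in both channels, and offset and background choices act mostly there.

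Counts of genes depended on the threshold by construction: 4636 were higher and 3312 lower at 1.5-fold, and 1734 and 682 at 3-fold. With the scanner software's ratio 3069 genes were higher and 2638 lower, the latter over 1.5 times the main count, and all 1739 genes called lower in the main setting were among them. That ratio had a median over genes 0.12 below the main one, and relative to this shift 3419 were higher and 2234 lower, so the shift accounts for part of the added lower genes and the cause of the rest was not tested. The value table gave 3019 and 2576, with the same shift of 0.12 downwards. Across the other settings, higher genes numbered 2628 to 3308 and lower genes 1440 to 1917, and the share of higher genes among calls was 63.2% in the main setting, 68.5% with median centring and 53.8% with the scanner software's ratio. Foxj1 shifted by less than 0.33 in all 8, and the spot SD stayed between 0.04 and 0.05. For Foxj1, with 1 probe well above background at both ages, several of these settings were no test. Neither filter setting nor the median over probes could change its value (2.19 in each). The scanner software's ratio and the value table gave the same 2.02.

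Of the 25 list medians, these shifted by 0.33 or more. Secretory airway cells came to 3.96 with the scanner software's ratio, 3.82 with the value table and 4.15 with probes well above background in both channels only; in the last case bounded genes dropped out. Axonemal dyneins came to 2.47 with the median over probes, from 2.93 over 33 values. Erythroid cells came to −0.55 over 13 values with the scanner software's ratio, from −0.18 over 14. These 2 starting values rest on other member sets than the medians in the Results (2.94 over 32 and −0.13 over 13). Nerve and mesothelium came to 0.50 with the value table. The cause was not tested for these shifts. With the scanner software's ratio, the basal cell median changed sign from 0.07 to −0.11 and the Notch median from 0.15 to −0.05 (0.00 and 0.07 relative to the shift of all genes), and the endothelium median of 1.11 came to 0.98 (1.09 relative to the shift), under 2-fold, as it did with the median over probes (0.93). Of 117 named genes beyond 2-fold, 111 kept that size with the median over probes (Dnah9, Dnah2, Icam1 and Ptprb were among those that did not), 116 with the scanner software's ratio or the value table, and 107 of 108 with both channels above background (Camkv did not). The other 4 settings kept all 117.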

Other observations

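Imprinted growth genes, which set fetal size, were spread over both directions: of 17 members, 2 were at least 2-fold higher at E18.5, 4 lower and 11 within 2-fold, with a median of −0.30 (percentile 6.69). The members farthest from 0 were all lower, with Grb10, an inhibitor of insulin signalling, at −2.61 (6.10-fold lower), the non-coding RNA H19 at −2.18 (4.54-fold lower) and Nnat at −2.04 (4.11-fold lower). Notch pathway genes, which govern the choice between secretory and ciliated fates in airways, showed 5 of 22 at least 2-fold higher, 2 lower and 15 within 2-fold, with a median of 0.15 (percentile 61.8). The ligands lay on both sides, Jag1 at 2.49 (5.62-fold, other probe 0.78) and Dll1 at −1.44 (2.71-fold lower). Target genes also lay on both sides, with Nrarp at 2.07, Hes1 at 1.61, Hey2 at 0.40, Hey1 at 0.16, Hes5 at −0.41 and Heyl at −0.71, the last 4 named after their values were seen. Immediate early and heat shock genes, which respond to handling of tissue, were mixed as well, with 5 of 16 at least 2-fold higher, 2 lower and 9 within 2-fold, and a median of 0.41 (percentile 83.7). Ier3 was at 2.54 (5.80-fold), Hspa1a at 2.47 (5.52-fold, with a probe at −0.01) and Jun at −1.97 (3.92-fold lower).

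The median of the axoneme list exceeded that of the intraflagellar transport and BBSome list by 2.51 (95% bootstrap interval over genes 2.10 to 2.83) and that of the regulator list by 3.26 (2.54 to 4.04). These differences, chosen after the medians were seen, describe the listed genes on this array. Within the mesenchyme list, 6 contractile genes of smooth muscle had a median of −1.48, with 6 of 6 below 0, and the other 27 members had a median of 0.32, with 12 below 0. That division was also made after the values were seen.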
